A study of Rattus norvegicus with 10 samples.

How the data were processed

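Testis RNA of adult male Wistar rats was measured by sequencing of poly(A) RNA. Per the labels' protocols, pregnant females were assigned to groups of 7 and fed corn oil, or the same oil with BDE-47 at 0.2 mg/kg body weight per day, from pregnancy day 8 to postpartum day 21. The labels put 5 testis libraries of male offspring at postnatal day 120 in each group. Per the labels' protocols, libraries were made with a stranded poly(A) kit from RNA with a high integrity score. The extraction text speaks of liver while the tissue labels and the library text speak of testis, so a list of liver genes was included as a check.

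Per the submitters' processing notes, reads were processed with TopHat2 and Cuffdiff 2.1.1 on the rat genome build rn5. How the libraries of a group were combined, the gene annotation, the strand setting of the counting and the treatment of reads with several matches are not given in the sources used here. The authors deposited a table with 1 value per group and locus, on the log2 scale of FPKM (fragments per kilobase of transcript, scaled to the fragments of the library). The table also holds the authors' log2 ratio, which equals the BDE-47 value minus the control value within 0.01. A log2 value of -10 marks the floor of the deposited table and was read as listed at 0. Such a 0 can be a failed estimate, since genes used by every cell, such as Rps6, a ribosomal protein gene, were also listed at 0 in both columns. The table holds no value per library, no p-value, no call of change and no read count, so the depth of each library is unknown and no error can be given.

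The plan, the gene lists and the rule for the genes named were set before the data were examined. The plan had limma and its set test camera on log2(FPKM + 1) for values per library, and no test of its own for a table of group values only. The table turned out to hold group values only, so no test was run and no p-value is given. The 2-fold rule and the random lists described here took the place of the tests and were chosen once the form of the table was known. Differences are the log2(FPKM + 1) of the BDE-47 column minus that of the vehicle column, which understates the difference of genes with low values. The direction rests on the column names. The libraries whose treatment label is BDE-47 have titles with a C code and those labelled vehicle have an X code, and the table does not show which libraries went into which column.

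The table holds 94827 loci, of which 20638 carry a gene name. One locus was kept for each content of the name field, the one with the highest mean of both columns, which gave 16915 names. Genes with a mean of at least 1 FPKM over both columns were compared, 11567 in all. Of these, 517 are merged loci that name several genes, and their value belongs to none of them alone. Of 17274 gene symbols in the table, 16850 were found as a symbol or synonym in a gene table of the rat assembly GRCr8, which was used only for names and for which genes lie next to each other. Coordinates are those of the deposited table, on rn5. They can span a bundle of overlapping genes, and antisense or neighbouring genes in a bundle cannot be told from each other by position. Paralogous genes share reads, so their values are uncertain.

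A gene is called higher or lower here if the columns differ by at least 2-fold on the log2(FPKM + 1) scale. This is a rule of size, not a test. There were 25 planned gene lists: genes of the histone-to-protamine exchange, sperm tail, acrosome, meiosis and spermatogonia; of Sertoli cells, Leydig cells and steroid synthesis, cholesterol synthesis, peritubular smooth muscle, endothelium, blood, macrophages and lymphocytes; of antigen presentation, the interferon response and inflammation; of epididymis and liver as other tissues; and of the xenobiotic response, antioxidant defence, thyroid hormone action, hormone receptors, insulin and mTOR signalling, apoptosis and immediate early genes. Of their 546 members, 522 were in the table. Lists with at least 4 compared genes (23 of 25) had their median set against the medians of 10000 random lists of the same size, matched on mean level in 20 bins and drawn with replacement. The percentile describes these group values and is not a p-value. A list outside the central 95% of random lists is called above or below the random range. Lists added after seeing the data were those of plasma cells, fat cells, ribosomal protein genes, fibroblast matrix and complement.

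The genes named are the 10 with the highest and the 10 with the lowest difference among those past 2-fold, in each list up to 4 members past 2-fold with the largest difference or otherwise the 2 with the highest mean, and always Prm1, Prm2, Tnp1, Tnp2, Star, Cyp11a1, Cyp17a1, Hsd17b3, Insl3 and Lhcgr. The 2-fold size takes the place of the test in this rule, and genes named only by a locus number were passed over. A few genes under this rule, and 1 interval of unnamed loci, are not reported here. Genes named outside the rule are said to be so. The calculation was tested on simulated columns with the real levels of the 11567 genes, a spread of 0.2 on the log2 scale and 50 genes at each size of change. The 2-fold rule recovered 96% of genes set 8-fold lower, 78% of genes set 4-fold lower and 100% of those set 4-fold or 8-fold higher, and it called 0.0176% of unchanged genes. The spread of 0.2 was assumed, since the real spread is unknown, and no shift between the columns was simulated. These shares check the calculation and are not error rates of the calls in the real columns. Alternatives were pseudocounts of 0.1 and 0.01, filters at a mean of 0.1 and 5 FPKM, median-of-ratios scaling, quantile normalization, leaving out the mitochondrial genome and the 10 most abundant loci with rescaling, and a 1.5-fold threshold, which took the place of the planned thresholds on adjusted p. Alternatives added after seeing the data were the deposited ratio without a pseudocount, loci that name 1 gene, every named locus, leaving out microRNA genes and genes listed at 0, and a 4-fold threshold. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.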

Results

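The adult testis was compared between male rats born to mothers given BDE-47, a brominated diphenyl ether used as a flame retardant, and rats born to mothers given the corn oil vehicle. The series title names male reproductive health in adulthood as its subject. Each group had 5 libraries at postnatal day 120, and the deposited table gives 1 FPKM value per group for each locus. The labels give no litter, so whether some libraries came from littermates is not known. The spread between animals is therefore not known for any value given here, no difference was tested, and the depth of the libraries is unknown. Summed over all 94827 loci, the vehicle column held 753397 FPKM and the BDE-47 column 799713 FPKM.

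Genes of the late steps of sperm formation were lower in the BDE-47 column, and genes of Sertoli cells, Leydig cells, macrophages and interferon-induced defence were higher. Of 11567 genes compared, 3480 were at least 2-fold higher in the BDE-47 column, 416 were at least 2-fold lower and 7671 lay within 2-fold. The median difference over all genes was 0.45 on the log2(FPKM + 1) scale, with quartiles of -0.20 and 1.17. Of the genes past 2-fold, 89.3% were higher in the BDE-47 column, a direction that rests on the column names and would turn, as all others here, if the columns were exchanged. This share depended on scaling: it was 57.1% after median-of-ratios scaling, which removed a shift of 0.52 log2 units, 50.4% after quantile normalization and 78.3% after the most abundant loci and the mitochondrial genome were left out. Median-of-ratios scaling centres the ratios and quantile normalization makes the columns equal in distribution, so both move the share toward balance by construction. They cannot show whether the excess of higher genes is real. The 10 most abundant loci held 12.9% of the summed FPKM in the vehicle column and 5.89% in the BDE-47 column. Prm1 alone, which encodes a protamine that packs DNA in the sperm head, held 5.74% and 2.03%. Of the 23 lists compared, 10 lay above and 2 below the central 95% of matched random lists, and 11 lay within it. These counts were also 10 and 2 after median-of-ratios scaling. That scaling shifts the lists and the random lists nearly alike, so the unchanged counts are no separate support.

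**Figure D1:**
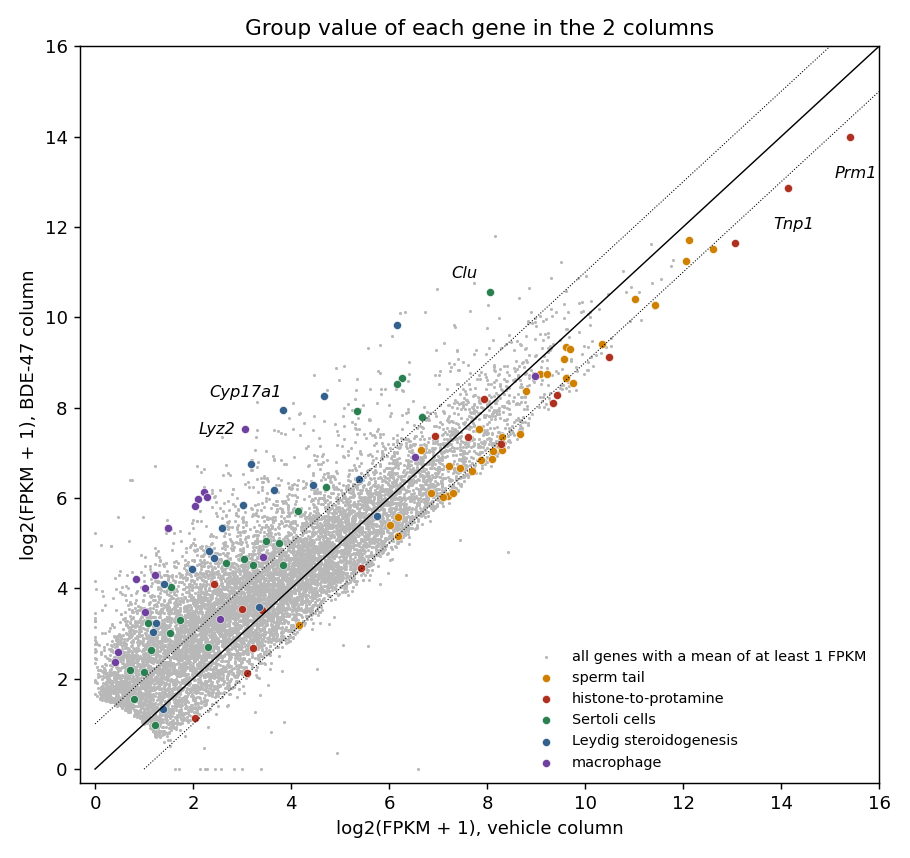
Each point is a gene with a mean of at least 1 FPKM, with log2(FPKM + 1) of the vehicle group on the horizontal axis and of the BDE-47 group on the vertical axis; the solid line marks equal values, the dotted lines a 2-fold difference, and colours mark 5 gene lists. Sperm tail and histone-to-protamine genes lie mostly on or below the solid line, among them Prm1 (43238 and 16271 FPKM), while most Sertoli, Leydig and macrophage genes lie above the upper dotted line.

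The protamine and transition protein genes, whose products replace histones on sperm DNA, had lower values in the BDE-47 column. Prm1 was at 43238 FPKM in the vehicle column and 16271 in the BDE-47 column (difference -1.41), Prm2 at 1438 and 556 (-1.37), Tnp1 at 18179 and 7434 (-1.29) and Tnp2 at 8599 and 3191 (-1.43). Prm1, Prm2 and Tnp2 share a bundle at chromosome 10:3511582-3783992 of build rn5, and Tnp1 lies at chromosome 9:80066299-80066908. Under quantile normalization Prm1 and Tnp1 showed no difference, because they held the same top ranks in both columns. Of the 17 genes in the histone-to-protamine list, 7 were at least 2-fold lower and 1 was at least 2-fold higher, with a median of -0.97, below the medians of all 10000 random lists. The member that was higher was the merged locus of Pygo2, a chromatin reader, and Shc1, a signalling adaptor, at 4.35 and 16.1 FPKM.

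Sperm tail genes were lower as a group. Of 34 genes, 14 were at least 2-fold lower and none was at least 2-fold higher, and the median of -0.94 was below those of all random lists. The largest differences were those of Spem1 (407 FPKM in the vehicle and 170 in the BDE-47 column), Tssk6, a kinase of the spermatid (315 and 133), Spata3 (274 and 116) and Tcp11 (867 and 372). Of 23 acrosome genes, 6 were at least 2-fold lower, and the median of -0.34 lay at the 10.8th percentile of random lists. Dkkl1 was at 832 and 377 FPKM, the merged locus of Acrbp and Ing4 at 276 and 126, Spaca4 at 147 and 68.6 and Lyzl4 at 83.9 and 39.4.

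Lists of genes of earlier germ cells lay within the random range. The median of 31 meiosis genes was 0.21, at the 49.7th percentile, with 3 genes at least 2-fold higher and 3 lower. Tex12 (12.1 and 29.9 FPKM) and Sycp1 (38.3 and 86.2), which encode parts of the synaptonemal complex of paired chromosomes, were higher in the BDE-47 column, as was the merged locus of Golph3l and Hormad1 (56.9 and 127), while the cyclin gene Ccna1 was lower (95.7 and 45.6). The median of 16 spermatogonia genes was 0.47, at the 45.5th percentile, with 3 genes higher and 1 lower. Kit, the receptor of differentiating spermatogonia, was at 2.08 and 12.0 FPKM, Dazl at 30.1 and 67.2, Rarg at 0.563 and 2.27 and Dmrtb1 at 89.3 and 43.1. After median-of-ratios scaling the medians of the meiosis and spermatogonia lists were -0.25 and -0.00, and after quantile normalization -0.43 and -0.03, so neither has a direction that holds across scalings. The meiosis list had 0 genes at least 2-fold higher and 9 lower after median-of-ratios scaling, and 2 and 4 after quantile normalization.

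**Figure D2:**
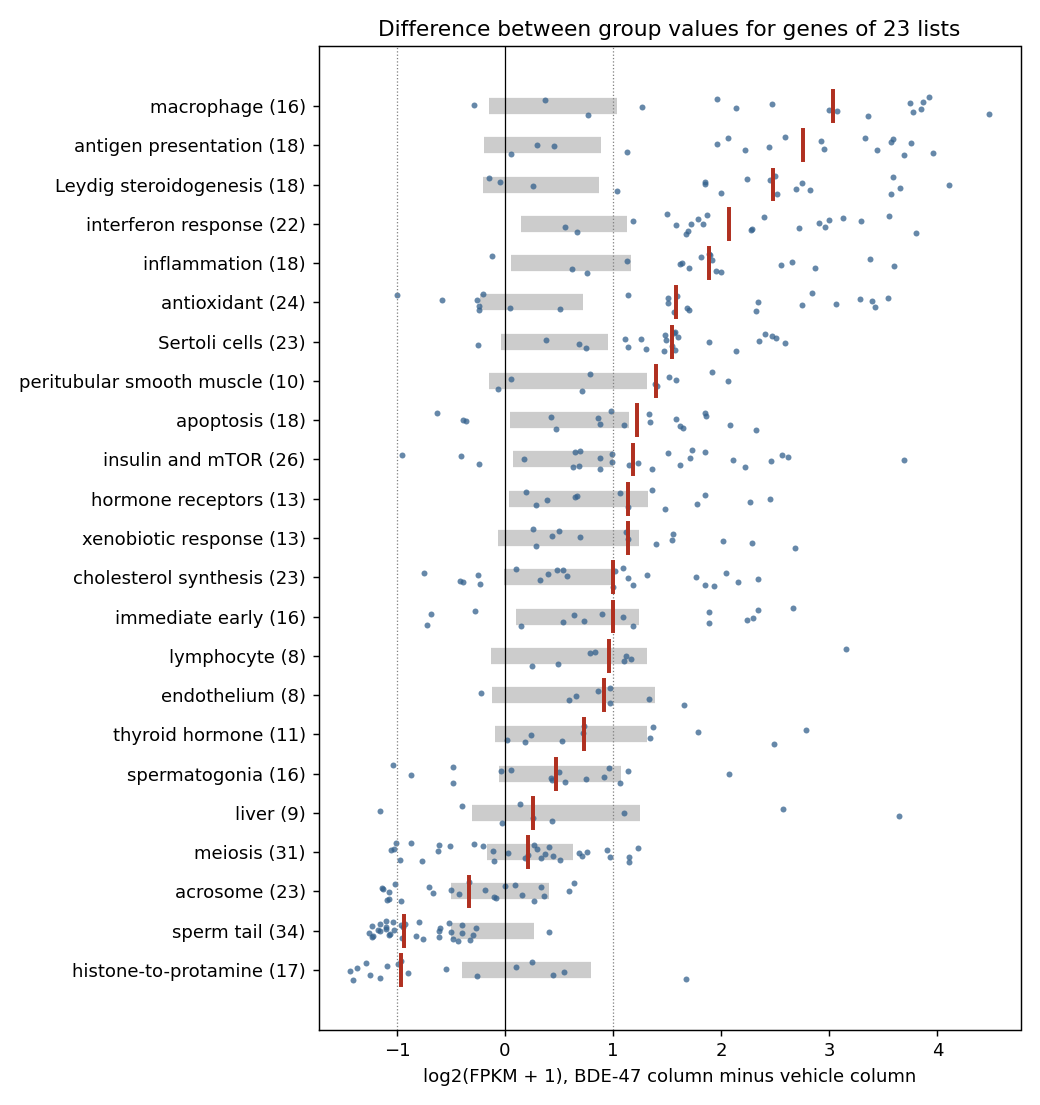
Points are the genes of 23 lists (number of genes in brackets), placed by the difference in log2(FPKM + 1) between the BDE-47 and vehicle columns; red bars are list medians and grey bands the central 95% of medians of 10000 random lists matched on mean level, with dotted lines at a 2-fold difference. The medians range from -0.97 for histone-to-protamine genes to 3.03 for macrophage genes.

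Sertoli cell genes, which serve the somatic cells that nurse the germ cells, were higher in the BDE-47 column. Of 23 genes, 19 were at least 2-fold higher and none was at least 2-fold lower, with a median of 1.54 above those of all random lists. Cldn11, of the tight junctions between Sertoli cells, was at 39.4 and 242 FPKM, Clu at 267 and 1520, the growth factor gene Kitlg at 1.95 and 15.3 and the protease gene Ctsl at 75.6 and 405. Peritubular smooth muscle genes had a median of 1.39 at the 98.6th percentile, with 6 of 10 genes at least 2-fold higher, among them Des (a difference of 2.07), Myl9 (44.0 and 169), Tpm2 (7.73 and 25.1) and Mylk (8.46 and 26.0). The other 4, named outside the rule, lay within 2-fold: Acta2 (25.1 and 41.6 FPKM), Cnn1 (1.33 and 3.01), Myh11 (13.7 and 14.3) and Actg2 (3.43 and 3.23). This list lay within the random range with pseudocounts of 0.1 and 0.01 and with the deposited ratio, at the 97.3rd, 97.0th and 97.0th percentiles. The median of 8 endothelial genes was 0.92, at the 73.6th percentile, with 2 genes at least 2-fold higher, Pecam1 (0.570 and 3.94 FPKM) and Egfl7 (1.10 and 4.29).

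Genes of the Leydig cells, which make testosterone, were higher in the BDE-47 column, 15 of 18 by at least 2-fold and none lower by that size. Their median of 2.48 was above those of all random lists. Cyp17a1, an enzyme of androgen synthesis at chromosome 1:273852186-273858182, was at 13.3 and 246 FPKM. The merged locus of Insl3, a Leydig cell hormone, and Jak3, a kinase of immune cells, at chromosome 16:19969813-19983164 was at 71.0 and 904. Hsd11b1 was at 24.4 and 304 FPKM and Tspo at 8.11 and 107. Star, which brings cholesterol into mitochondria, was at 11.6 and 71.0, Cyp11a1, the first enzyme of steroid synthesis, at 20.8 and 77.7, Hsd17b3, which makes testosterone, at 1.37 and 8.46, and Lhcgr, the receptor of luteinizing hormone, at 2.93 and 20.5. The 3 genes within 2-fold, named outside the rule, were Hsd3b6 (53.1 and 47.8 FPKM), Por (9.13 and 11.1) and Srd5a1 (1.60 and 1.53). Another locus, which merges Hsd3b, Hsd3b1 and Hsd3b6, was at 7.16 and 56.5. Of 23 cholesterol synthesis genes, 12 were at least 2-fold higher and none lower, with a median of 1.00 at the 97.3rd percentile, within the random range. Among them were Msmo1 (4.44 and 26.5 FPKM), Ebp (1.49 and 10.1) and Nsdhl (0.871 and 6.15). After quantile normalization the cholesterol synthesis list had a median of 0.17, with 5 genes at least 2-fold higher and 1 lower.

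Macrophage genes showed the highest median of the planned lists, 3.03, above those of all random lists, with 13 of 16 genes at least 2-fold higher in the BDE-47 column. Lyz2, a lysozyme gene, was at 7.31 and 184 FPKM, and C1qa (3.32 and 61.8), C1qb (1.80 and 39.4) and C1qc (3.66 and 69.6), of the first complement component, differed by similar amounts. Aif1, which is also used as a macrophage marker and is named outside the rule, was at 505 and 413 FPKM. Antigen presentation genes had a median of 2.75, with 15 of 18 at least 2-fold higher. Cd74, the chaperone of class II molecules, was at 17.0 and 232 FPKM, RT1-Da at 5.78 and 90.5, B2m, the light chain of class I molecules, at 54.9 and 671, and the merged locus of RT1-A1 and RT1-A2 at 29.2 and 468. Interferon response genes had a median of 2.07, with 20 of 22 at least 2-fold higher, led by Ifi27 (14.6 and 217 FPKM), Gbp2 (1.42 and 27.5), Ifi44 (1.01 and 18.6) and Isg15 (0.547 and 12.5). Inflammation genes had a median of 1.89, with 15 of 18 at least 2-fold higher, led by the chemokine genes Cxcl12 (4.35 and 63.6 FPKM), Ccl11 (6.06 and 72.5) and Ccl2 (0.101 and 7.01) and by the adhesion gene Vcam1 (3.58 and 27.9). The medians of the antigen presentation, interferon and inflammation lists were each above those of all random lists. The median of 8 lymphocyte genes was 0.97, at the 81.6th percentile, with Cd4, which rat macrophages also express, at 1.62 and 22.3 FPKM, Il2rb with a difference of 1.16, Cd8a at 1.17 and 3.71 and Cd3g at 0.655 and 2.55. All 3 loci of the blood list that were compared were higher, the merged beta globin locus at 11.3 and 46.5 FPKM, Alas2 at 7.46 and 23.1 and the merged alpha globin locus at 22.8 and 62.7.

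Of 24 antioxidant genes, 16 were at least 2-fold higher and none was at least 2-fold lower, with a median of 1.58 above those of all random lists. Txn1 was at 65.3 and 771 FPKM, Gpx3 at 0.157 and 11.4, the cystine transporter gene Slc7a11 at 1.45 and 24.8 and Gpx1 at 11.5 and 120. Gpx4, which in testis makes a structural protein of the sperm midpiece, was at 1938 and 969 FPKM and is named outside the rule. Insulin and mTOR signalling genes had a median of 1.19 at the 99.7th percentile, with 14 of 26 at least 2-fold higher, led by Igfbp2 (17.1 and 234 FPKM), Igf1 (4.26 and 31.3), Igfbp4 (1.13 and 11.6) and the kinase gene Akt1 (6.45 and 39.9). After quantile normalization this list had a median of 0.64, at the 99.9th percentile, with 7 genes at least 2-fold higher and 1 lower. Apoptosis genes had a median of 1.22 at the 98.6th percentile, with 10 of 18 at least 2-fold higher, among them the merged locus of Bax and Ftl1 (123 and 617 FPKM), Bbc3 (0.363 and 3.94) and Cdkn1a (4.32 and 18.1). The apoptosis list lay within the random range with a filter at a mean of 5 FPKM, at the 80.7th percentile, and without merged loci, at the 94.1st. After quantile normalization its median was 0.49, at the 97.6th percentile, with 4 genes at least 2-fold higher and 1 lower.

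The other lists of signalling and response genes lay within the random range, apart from the settings named here. Xenobiotic response genes had a median of 1.14 at the 95.4th percentile, with 8 of 13 at least 2-fold higher, and lay above the range after quantile normalization, at the 98.4th percentile. Among these genes were Cyp1b1 (4.50 and 34.3 FPKM), a merged locus of 8 Ugt1a genes (9.00 and 47.8), Abcc3 (0.483 and 4.99) and the merged locus of Gsta2 and Gsta5 (15.9 and 48.5). Hormone receptor genes had a median of 1.14 at the 91.1st percentile, with 8 of 13 at least 2-fold higher, among them Ghr (0.732 and 7.31 FPKM), Prlr (1.28 and 7.21) and Nr3c1 (1.21 and 6.54) beside Lhcgr; with pseudocounts of 0.1 and 0.01 and with the deposited ratio this list lay above the range, at the 98.1st, 98.7th and 98.8th percentiles. Thyroid hormone genes had a median of 0.73 at the 64.5th percentile, with 5 of 11 at least 2-fold higher, among them Thrsp (0.013 and 5.98 FPKM), Thra (1.78 and 14.6), Rxra (0.973 and 5.82) and Rxrg (0.166 and 2.01). Immediate early genes had a median of 0.99 at the 86.7th percentile, with 8 of 16 at least 2-fold higher, led by Ier3 (1.21 and 13.0 FPKM), Junb (1.64 and 12.4), Myc (0.157 and 4.69) and Ier2 (0.563 and 6.36). This list lay above the range with a pseudocount of 0.01, at the 98.0th percentile, and with the deposited ratio, at the 98.3rd. After quantile normalization, 4 xenobiotic response, 2 hormone receptor, 3 thyroid hormone and 6 immediate early genes were at least 2-fold higher. The medians of these lists were then 0.70, 0.35, 0.10 and 0.28.

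Genes of other tissues gave no common direction. Of the epididymis list, 2 genes reached a mean of 1 FPKM, Spink8 (103 and 145 FPKM) and Crisp1 (2.43 and 3.73), with a list median of 0.48. The difference of Spink8 was -0.03 after median-of-ratios scaling and that of Crisp1 was -0.39 after quantile normalization. Of the liver list, 9 genes were compared, with a median of 0.26 at the 36.3rd percentile and of -0.19 after median-of-ratios scaling and -0.43 after quantile normalization. Hp, which encodes haptoglobin, was at 23.1 and 142 FPKM, Cyp2e1 at 0.774 and 2.81, and Serpina1 at 1479 and 662.

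The 10 genes with the highest difference were Testin, Fabp4, the merged locus of C4a and C4b, Oraov1, Tnfrsf12a, Wnt4, Timp1, Ifi27l2b, S100a11 and Car3. Testin, at chromosome 17:6435950-6467371, was at 0.637 and 83.9 FPKM (difference 5.70), Fabp4, a fatty acid binding protein of fat cells and macrophages, at 0.683 and 83.3, and C4a with C4b, of the complement system, at 1.35 and 103. Tnfrsf12a was at 0.382 and 47.2 FPKM, the signalling gene Wnt4 at 0.0836 and 30.3, Timp1, a protease inhibitor, at 8.82 and 278, Ifi27l2b at 4.99 and 163, S100a11 at 3.23 and 103, and Car3, a carbonic anhydrase, at 0.261 and 29.9. Oraov1 was listed at 0 in the vehicle column and at 36.3 in the BDE-47 column. For 4 of these 10 names the table holds another locus of the same coordinates with a smaller difference, such as Testin at 0.824 and 1.01 FPKM and Fabp4 at 0.493 and 0.688.

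The 10 genes with the lowest difference were mostly loci with uncertain values. RT1-A1, Mir153, Hist1h4m, Mir1949, Mir9-3 and Mir6333 were listed at 0 in the BDE-47 column, from 95.7, 9.45, 7.01, 6.11, 4.96 and 4.47 FPKM in the vehicle column. The RT1-A1 locus shares chromosome 20:7413077-7478156 with the merged RT1-A1 and RT1-A2 locus, which was higher in the BDE-47 column. Capn2 was at 29.4 and 0.285 FPKM, while another Capn2 locus with the same coordinates was at 5.43 and 8.94. Cd99l2 was at 46.2 and 5.62 FPKM, Ankrd34b at 13.5 and 1.06, and the merged locus of the imprinted RNA gene H19 and Mir675 at 11.1 and 0.768.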

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

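The test of short loci was chosen after the result was seen; the test of plasma cell genes was written before its members were looked at. Some loci without a gene name, which enter no count of genes above, held signal in the BDE-47 column and were listed at 0 or low in the vehicle column. A listed 0 can be a failed estimate and does not show that signal was absent. Of 19450 unnamed loci with a mean of at least 1 FPKM, 77 were listed at 0 in the vehicle column and at 10 FPKM or more in the BDE-47 column, against 2 in the opposite direction. Of the 19450, 3718 were at least 2-fold higher and 453 at least 2-fold lower. Over all loci of the table, 2357 were listed at 0 in the vehicle column only and 213 in the BDE-47 column only. All 9 loci of the mitochondrial genome had a higher value in the BDE-47 column, by 0.87 to 2.22 on the log2(FPKM + 1) scale. Between Olr410 and Olr411 on chromosome 3, unnamed loci summed to 83.7 FPKM in the vehicle and 2106 in the BDE-47 column, of which loci that span at least 400 bp made up 41.4 and 1355. The median difference of 2.95 over all 38 loci compared there was as high as that in the heavy chain interval described next (2.94). In the GRCr8 gene table these olfactory receptor genes have 0 genes between them, so what lies there in rn5 was not identified.

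Between Crip1 and Zfp386 on chromosome 6, where the GRCr8 table lists 146 variable segments and 4 constant regions of the heavy chain, unnamed loci summed to 53.1 FPKM in the vehicle and 2461 in the BDE-47 column, of which loci that span at least 400 bp made up 38.2 and 1090 and 1 locus of 96 bp, listed at 0 in the vehicle column, 929 in the BDE-47 column. Between Olr1570 and Hira on chromosome 11, the place of the lambda chain, the sums were 18.9 and 232. The 34 loci of these intervals that span at least 400 bp had a median difference of 4.39. The central 95% of random sets of unnamed loci of that span had medians from -0.28 to 0.38. The difference is therefore not confined to loci of short span, which still hold a share of the heavy chain sum. Span is distance along the genome, not transcript length, so the test cannot decide on inflated FPKM of short transcripts. RNA of plasma cells is a candidate source: 8 plasma cell genes had a median of 1.66, at the 99.7th percentile of random lists, with the most abundant members Xbp1 at 4.99 and 38.1 FPKM and Txndc5 at 4.17 and 36.0, but 5 of the 15 listed genes were at 1 FPKM or more in the vehicle column too, and the macrophage, antigen presentation, interferon and inflammation lists were as high. Whether 1 library or all 5 carried this signal, and whether it goes with the exposure, stays open, since the table holds 1 value per group.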

How the results depend on the processing

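The 4-fold threshold, the deposited ratio, single-gene loci, every named locus and leaving out microRNA genes and genes at 0 were chosen after seeing the data. Against 3480 higher and 416 lower genes, median-of-ratios scaling gave 2233 and 1675, and quantile normalization 1658 and 1630. Leaving out the 10 most abundant loci and the mitochondrial genome gave 830 lower genes. Pseudocounts of 0.1 and 0.01 gave 4047 and 4090 higher and 553 and 578 lower genes. A filter at 5 FPKM gave 2227 higher genes, with fewer genes compared (8439), and a 1.5-fold threshold gave 1502 lower genes. A 4-fold threshold gave 984 and 18. Median-of-ratios scaling and quantile normalization balance the columns by construction. For the scalings the cause was not tested beyond this and the shift of 0.52 that median-of-ratios scaling removes. The counts of lists above and below the random range stayed at 9 to 11 and at 2 in the settings run. Across these settings 8 lists stayed above and 2 below, and 5 changed side in at least 1 setting. No named gene past 2-fold and no list outside the random range changed sign, though Prm1 and Tnp1 came to 0 under quantile normalization. Of 228 list medians under alternatives, 43 moved by over 1.5-fold, as did 168 of 1253 values of named genes. Leaving out each library, other variance models, library weights, count tests, camera and fry and adjusted p thresholds were not run. No paired analysis was possible because the table holds 1 value per group. Depth is unknown, so the precision of low values cannot be given.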

Other observations

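The tests of scaling, germ cell share, background and epididymis reported in this part were chosen after the result was seen, as were the matrix, complement and ribosomal lists; the fat cell test was written before its members were looked at. Connective tissue and complement genes, which no planned list covered as such, were higher in the BDE-47 column. Of 17 fibroblast matrix genes, 15 were at least 2-fold higher, with a median of 2.05: Bgn was at 8.69 and 162 FPKM, Dcn at 5.13 and 89.9, Col3a1 at 1.74 and 22.8 and Sparc at 32.7 and 254. Of 15 complement genes, 14 were at least 2-fold higher, with a median of 3.33, among them Serping1 at 3.66 and 99.0 FPKM; the list shares 3 genes with the macrophage list. Both medians were above those of all random lists, and both lists were put together after some members had been seen.

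Genes placed on the X chromosome in rn5 had a higher median difference than others. The median of 343 such genes was 1.10, against 0.44 for 11224 genes placed on autosomes, and above those of all 10000 matched random sets (central 95% from 0.45 to 0.71). Both sets follow the placement in rn5, which was not checked gene by gene. After median-of-ratios scaling the medians were 0.66 and -0.02. Among ribosomal protein genes, Rpl39 (74.0 and 1097 FPKM), Rps4x (32.7 and 484) and Rpl36a (15.3 and 184) on chromosome X and Rpl10 (46.5 and 639), placed on chromosome 1 in rn5, had a median of 3.80, against 1.03 for 69 other ribosomal protein genes, each with a difference below the lowest of these 4 (3.50). Rpl39l, an autosomal copy of Rpl39 used in spermatids, was at 1833 and 1510 FPKM.

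On the log2(FPKM + 1) scale the Sertoli, Leydig, peritubular and macrophage lists lay above the random range. The sperm tail and histone-to-protamine lists lay below it, and the endothelial, lymphocyte and acrosome lists within it. With the deposited ratio the peritubular list also lay within the range, at the 97.0th percentile. Its median was then 1.575, close to those of the endothelial (1.585) and lymphocyte lists (1.66). The peritubular list is thus set apart from the endothelial and lymphocyte lists only in some settings. The gap between the Leydig and sperm tail medians on the log2(FPKM + 1) scale was 3.41. A single scaling factor shifts all genes nearly alike, so this gap argues against such a factor as the only cause. The central 95% of gaps between matched random lists ran from -0.22 to 1.13. This comparison adds no separate support, since the 2 lists were chosen after they were seen to lie at opposite ends. How much a factor adds to the difference of each list is not decided. A lower share of haploid germ cells alone would raise every other cell type alike, if the genes compared are silent in germ cells. In 5 of 10 pairs of 5 somatic lists the quartile ranges of the log2 ratio in the authors' deposited table did not overlap. Macrophage genes (2.83 to 4.23) lay apart from Sertoli (1.39 to 2.40), peritubular (0.84 to 1.88) and endothelial genes (0.93 to 2.01). Leydig genes (2.05 to 3.20) lay apart from the peritubular and endothelial ones. Germ cell signal in some members would also set lists apart. The endothelial list shares 1 locus with the acrosome list, the merged locus of Eqtn and Tek (88.0 and 133 FPKM). Which members germ cells express was not checked, so this comparison does not decide on that explanation. On the log2(FPKM + 1) scale the macrophage (1.79 to 3.79) and Sertoli ranges (1.20 to 2.01) overlapped. On that scale the Sertoli and endothelial ranges (0.64 to 1.06 for the latter) lay apart, while their ranges of the deposited ratio overlapped. Which lists lie apart thus depends on the scale, which understates the difference of genes with low values. A constant background of genomic DNA in the BDE-47 libraries is argued against too, since 90% of the 596 olfactory and vomeronasal receptor loci above 0 in a column (of 1516) were higher by at most 0.177 FPKM or not higher, against a lower quartile of 4.56 FPKM for Sertoli genes. Unspliced RNA, a lower share of haploid germ cells together with a change in Leydig cells and macrophages, a difference between single animals, an exchange of the columns, which would turn every direction, and an effect of the exposure stay open and untested.

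Fat cell genes were seen among the highest differences. Beside Fabp4 and Car3, and named after their values were seen, Lpl was at 0.114 and 13.2 FPKM, Cfd at 4.44 and 65.3, Retn at 0.013 and 5.17, Lep at 0.0172 and 1.82 and Adipoq at 6.32 and 16.4. For fat tissue taken along with the testis the test did not decide: 8 further fat cell genes had a median of 0.97, at the 94.9th percentile of random lists. Of these 8 genes, 4 had a difference above 0. Mrap (1.18 and 21.7 FPKM) and Angptl4 (1.33 and 12.4) were higher, while Lipe (85.6 and 46.2) and Aqp7 (317 and 165) had lower values, within 2-fold. In the vehicle column, 8 of the 15 listed genes were at 1 FPKM or more. Epididymis taken along is argued against, since the highest of its 6 abundant genes in the BDE-47 column, Crisp1, was at 3.73 FPKM; Spink8, a list member outside these 6, was at 103 FPKM in the vehicle column and 145 in the BDE-47 column. An effect of the exposure on these genes was not tested.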
